A study of Cryptococcus neoformans H99 and Malassezia restricta with 5 samples.

How the data were processed

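RNA from 2 basidiomycete yeasts was sequenced after growth with or without lauryl betaine, a zwitterionic surfactant. Cryptococcus neoformans H99, an encapsulated pathogen, was grown in YPD medium for 3 hours at 30 °C without the compound, with 4.5 µg/mL or with 9.0 µg/mL. Malassezia restricta KCTC 27527, a lipid-dependent skin yeast, was grown in mDixon medium for 12 hours at 34 °C without the compound or with 3.0 mg/mL. The labels give 5 samples in 5 groups, 1 library per group, so no spread between replicates, p-value for a difference between conditions or count of significant genes can be given. The p-value for neighbouring M. restricta genes comes from permuting gene order within the libraries.

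Per the labels' protocols, RNA was extracted with a yeast RNA kit and libraries were made with a stranded total RNA kit. The submitters' processing notes name Trimmomatic 0.36, TopHat2, featureCounts and Subread. The genome builds, annotations and strand setting are not given in the sources used here. Per the file headers, the authors deposited 1 table per species with TPM, the length-scaled transcript abundance, for each library and their own fold change, the ratio of treated to control TPM. This unit divides reads by gene length and scales each library to a fixed sum, so a lower share of abundant genes raises the values of the others, and the depth of each library is unknown. The deposited TPM have 2 decimals. The deposited ratio matched the quotient of the TPM columns within a relative tolerance of 1e-09 for all 6964 C. neoformans genes and all 4390 M. restricta genes that have one. It is blank for 11 C. neoformans genes listed at 0 in the control. The 2 tables were normalized separately, so TPM were not compared between species.

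The value analysed was log2(TPM + 1) of one library minus that of another, which understates the change of low genes. Genes with a mean TPM of at least 5 over the libraries of their table were kept, 6197 of 6975 in C. neoformans and 4383 of 4390 in M. restricta. A gene was counted as apart when its log2 change reached 1 in either direction, that is 2-fold. This is a limit of size, not of significance. Because the median of all C. neoformans genes lay above 0 at both doses, changes of single genes are given relative to that median and called relative log2 changes.

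All 6975 C. neoformans locus tags matched the protein-coding genes of the RefSeq H99 gene table, assembly CNA3, which was used for gene length, neighbouring genes and the mitochondrial genome. Neither this table nor the deposited files pair locus tags with symbols or products. Gene groups were therefore lists of H99 locus tags written, before the data were examined, from general knowledge of published H99 gene functions. The functions named here are such background and were not checked against an annotation. Of 30 lists, 13 held locus tags, 92 in all, and were used. The other 17 were defined by product wording only and could not be applied. M. restricta identifiers matched no table, so its genes are named by identifier and no gene groups were formed.

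Named genes followed a rule fixed together with the lists. They are the 2 genes highest and the 2 lowest in each comparison (in C. neoformans by the smaller change over both doses), members of the lists with the largest changes, and every member of the ergosterol and cell wall lists. A list with 5 or more members above the filter was described by the percentile of its median change among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these libraries and is not a test. Mean expression was taken over all C. neoformans libraries, the treated ones included. Because both C. neoformans comparisons share 1 control library, their correlation was set beside 100 simulations of unchanged libraries whose spread per expression bin was taken from the difference between the doses. Intervals of medians over genes are 95% bootstrap intervals from 2000 resamples of genes. They cover neither counting error nor variation between cultures.

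The counting and percentile code was tested on simulated data with 200 genes altered by known folds. For both the C. neoformans comparison at 4.5 µg/mL (5842 genes run) and the M. restricta comparison (4384 genes run), 100% of genes altered by 4-fold or 8-fold were recovered, and no unaltered gene was counted. Of genes altered by exactly 2-fold, 44% and 42% were counted. The simulated noise was far smaller than the 2-fold limit, so full recovery and no false count were all but fixed in advance. Only genes well above the filter were altered, and changes were centred on the median gene. These figures check the code and give no error rate for the counts reported below. Alternatives fixed in advance were a pseudocount of 0.1 or 5 TPM, a mean TPM of at least 1 or 20 or no filter, centring on the median gene, and rescaling without the 50 most abundant genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.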

Results

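Transcript levels were measured by RNA sequencing in C. neoformans H99 without lauryl betaine, at 4.5 µg/mL and at 9.0 µg/mL, and in M. restricta KCTC 27527 without the compound and at 3.0 mg/mL. Each condition was represented by 1 library. The values below are therefore single measurements without replicate error, and every difference compares libraries rather than conditions. The C. neoformans table held 6975 genes with a median TPM of 20.7 in the control, 26.7 at 4.5 µg/mL and 31.1 at 9.0 µg/mL. The M. restricta table held 4390 genes with a median TPM of 101 in the control and 90.9 after treatment. TPM have a fixed sum per library, so the sequencing depth behind them is unknown.

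The first question was how C. neoformans transcript levels differed after 3 hours in lauryl betaine. Of 6197 genes, 389 were at least 2-fold higher and 18 at least 2-fold lower at 4.5 µg/mL. At 9.0 µg/mL, 926 were higher and 18 lower. In all, 358 genes were higher and 7 were lower at both doses, and no gene was 2-fold apart in opposite directions. The genes highest at both doses were CNAG_02087 and CNAG_03713. CNAG_02087 stood at 5.43 TPM in the control, 637 TPM at 4.5 µg/mL and 802 TPM at 9.0 µg/mL, and CNAG_03713 at 1.48, 153 and 392 TPM. The lowest were CNAG_00597, with 51.4, 17.6 and 4.30 TPM, and CNAG_04217, with 28.3, 5.40 and 9.78 TPM.

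Most genes lay above 0, 79.0% of them at 4.5 µg/mL and 83.25% at 9.0 µg/mL. The median gene was 0.30 higher on the log2 scale at 4.5 µg/mL (95% bootstrap interval over genes 0.29 to 0.31) and 0.46 higher at 9.0 µg/mL (0.44 to 0.47). Over the same libraries the 50 most abundant genes went from 38.1% of all TPM in the control to 32.1% and 28.7%, and 46 of the 50 were lower at each dose. With changes centred on the median gene, 217 genes were higher and 73 lower at 4.5 µg/mL, and 376 higher and 148 lower at 9.0 µg/mL. The share of higher genes among those 2-fold apart thus went from 95.6% to 74.8% and from 98.1% to 71.8%. Centred, 196 genes were higher and 36 lower at both doses, so that 84.5% of them were higher against 98.1% without centring. Changes of single genes below are relative to the median gene.

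Among the 6 lists with 5 or more genes above the filter, sterol synthesis had the highest median at both doses. Of 19 genes listed for ergosterol, the main fungal membrane sterol, and its isoprenoid precursors, 16 were at least 2-fold higher at each dose, and 14 still were relative to the median gene. The summed TPM of the list was 1737 in the control, 10611 at 4.5 µg/mL and 12737 at 9.0 µg/mL, which is 6.11 and 7.33 times the control. The median relative log2 change was 1.87 at 4.5 µg/mL and 1.92 at 9.0 µg/mL. At both doses the list median exceeded all 10000 random lists matched on expression.

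The member with the highest relative change at both doses was CNAG_01737, a sterol methyl oxidase. It stood at 133 TPM in the control, 3138 TPM at 4.5 µg/mL and 4409 TPM at 9.0 µg/mL, a relative log2 change of 4.25 and 4.58. CNAG_02830, a sterol side-chain reductase, was 3.04 and 3.53 higher, and CNAG_00117, a sterol ring reductase, 2.99 and 3.31. CNAG_00854, a sterol isomerase, was 3.04 and 2.88 higher, CNAG_00519, a sterol desaturase, 2.90 and 2.92, and CNAG_06644, a second sterol desaturase, 1.87 and 2.24. CNAG_00040, the lanosterol demethylase that azole drugs inhibit, stood at 58.9, 367 and 468 TPM, a relative log2 change of 2.32 and 2.52. CNAG_01129, lanosterol synthase, was 2.35 and 2.76 higher, CNAG_03819, sterol methyltransferase, 2.11 and 1.92, and CNAG_06829, squalene epoxidase, the allylamine target, 1.45 and 1.49.

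Values also differed among genes that supply sterol precursors. CNAG_02918, acetyl-CoA acetyltransferase, was 2.31 and 2.04 higher, CNAG_02084, farnesyl diphosphate synthase, 1.54 and 1.56, and CNAG_03311, hydroxymethylglutaryl-CoA synthase, 1.33 and 1.05. CNAG_06534, hydroxymethylglutaryl-CoA reductase, was 0.93 and 1.02 higher, and CNAG_05125, mevalonate diphosphate decarboxylase, 1.10 and 0.80. CNAG_04605, a sterol dehydrogenase, was 0.88 and 0.81 higher. The remaining members had lower values. Their place in the list is the least certain, but no member was checked against an annotation, so they count like the others. CNAG_07780, listed as squalene synthase, stood at 0.42 and 0.037, and CNAG_07437, listed as a ketosteroid reductase, at 0.047 and -0.11. CNAG_00265, listed as isopentenyl diphosphate isomerase, was lower, at -0.64 and -1.03.

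**Figure D1:**
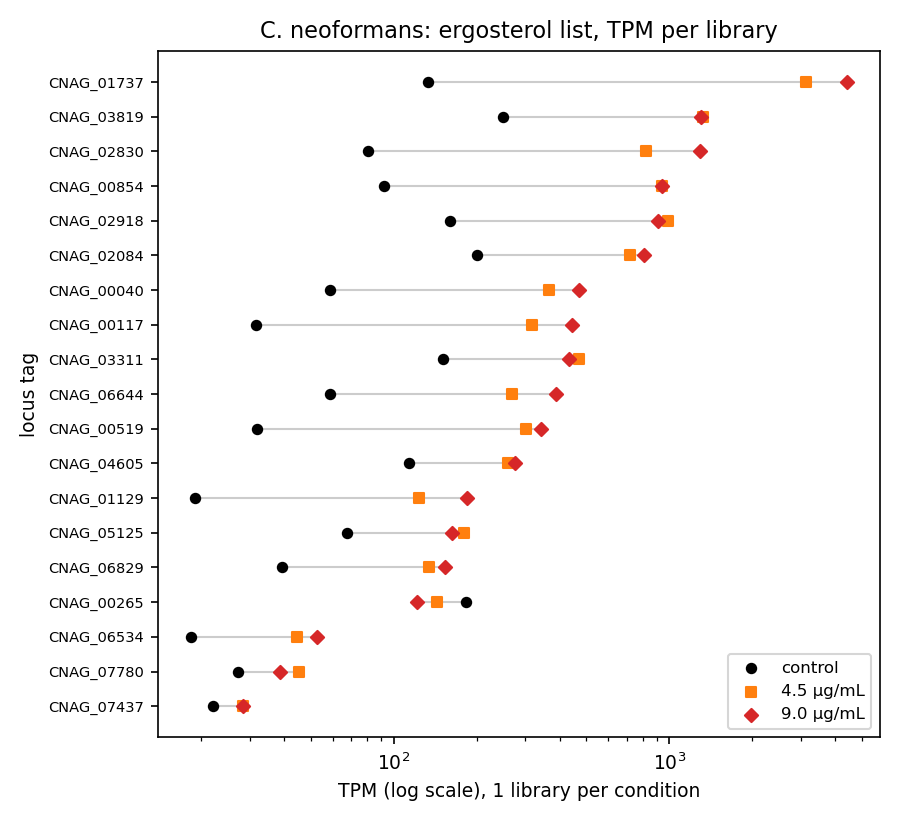
TPM (log axis) of the 19 listed ergosterol and isoprenoid genes in the C. neoformans control, 4.5 µg/mL and 9.0 µg/mL libraries, 1 point per library. CNAG_01737 reached 4409 TPM against 133 TPM in the control, and CNAG_00265 alone was below its control value at both doses.

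Of 3 listed sterol and hypoxia regulators, 1 was far from the median gene. CNAG_04804, the sterol-responsive transcription factor, stood at 7.77 TPM in the control, 127 TPM at 4.5 µg/mL and 183 TPM at 9.0 µg/mL, a relative log2 change of 3.57 and 3.93. CNAG_01580, the sterol sensor that escorts it, was at 0.43 and 0.89, and CNAG_05721, the protease that activates it, at 0.11 and 0.40.

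All 3 listed multidrug transporters were at least 2-fold higher at both doses, also relative to the median gene. CNAG_00869, an ABC transporter, had 4.63 TPM in the control, 31.3 TPM at 4.5 µg/mL and 120 TPM at 9.0 µg/mL, a relative log2 change of 2.22 and 3.98. CNAG_00796 had 7.87, 41.5 and 92.5 TPM, a change of 1.96 and 2.94. CNAG_00730, the main azole efflux pump, had 37.1, 108 and 134 TPM, a change of 1.22 and 1.37.

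**Figure D2:**
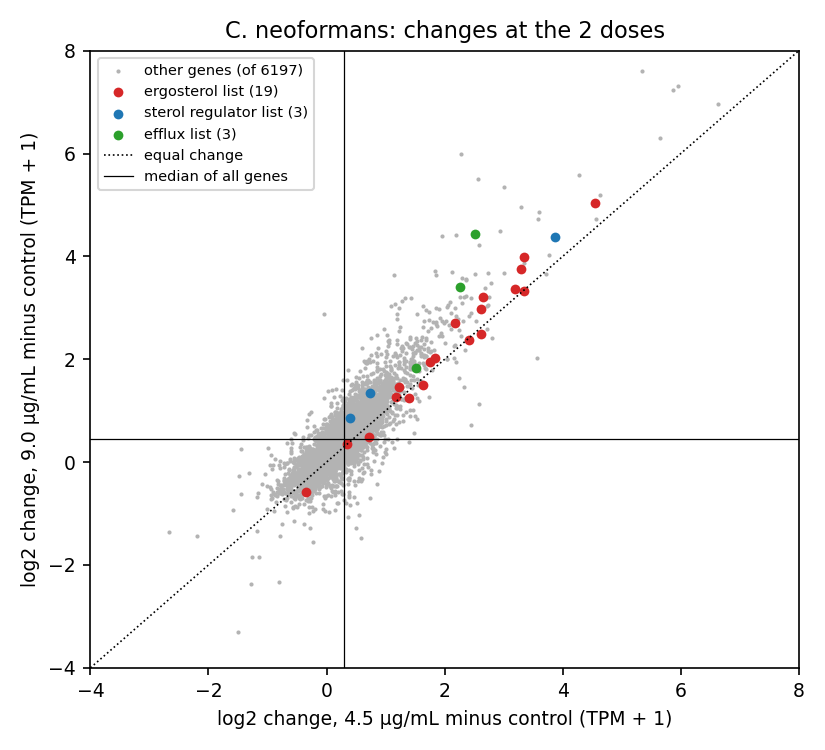
Log2 change of TPM + 1 from control at 4.5 µg/mL (x axis) and 9.0 µg/mL (y axis) for 6197 C. neoformans genes, 1 point per gene, with the ergosterol, sterol regulator and efflux lists in colour and solid lines at the medians of all genes (0.30 and 0.46). Points above the dotted line had the larger change at 9.0 µg/mL.

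Metal genes showed a pattern that differed between the doses. Of 17 listed iron, copper and zinc genes above the filter, 3 were at least 2-fold higher at each dose and 1 was 2-fold lower at 9.0 µg/mL. Relative to the median gene, 2 were higher at 4.5 µg/mL, and 1 was higher and 1 lower at 9.0 µg/mL. The median relative log2 change was 0.54 at 4.5 µg/mL, above all 10000 matched random lists, and 0.19 at 9.0 µg/mL, at percentile 98.3. CNAG_01653, a secreted heme-binding mannoprotein, stood at 599, 2832 and 1868 TPM in the control, 4.5 µg/mL and 9.0 µg/mL libraries. CNAG_01242, an iron-responsive regulator, stood at 20.6, 61.8 and 50.6 TPM, and CNAG_07751, a siderophore transporter, at 23.4, 53.8 and 49.2 TPM. CNAG_06242, an iron permease, stood at 238, 455 and 236 TPM, and CNAG_02958, a ferroxidase, at 34.7, 64.9 and 30.7 TPM. CNAG_00979, a copper transporter, went the other way, with 795, 608 and 344 TPM. CNAG_06976, a ferric reductase, was under the filter, with 0.62, 4.62 and 3.96 TPM.

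Stress genes were divided. Of 8 listed chaperones, CNAG_01446, a small membrane-associated heat shock protein, was the outstanding member, with 1807 TPM in the control, 12025 TPM at 4.5 µg/mL and 15104 TPM at 9.0 µg/mL. CNAG_03892, a mitochondrial co-chaperonin, stood at 1289, 1555 and 3072 TPM. CNAG_06443, the chaperone of the endoplasmic reticulum, stood at 502, 979 and 537 TPM, and CNAG_06150, the cytosolic chaperone Hsp90, at 608, 667 and 469 TPM. The median relative log2 change of the list was -0.064 at 4.5 µg/mL and -0.16 at 9.0 µg/mL, at percentiles 89.5 and 88.5 of the matched lists, while its mean was 0.35 and 0.16. Median and mean thus differed in sign. The negative list medians follow from subtracting the median of all genes. Without that step the chaperone medians were 0.23 at 4.5 µg/mL and 0.29 at 9.0 µg/mL. The matched random lists had medians of 0.012 and -0.0018.

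Of 10 oxidative stress genes above the filter, 1 was at least 2-fold higher at 4.5 µg/mL and 3 at 9.0 µg/mL. Relative to the median gene, 1 was higher and 1 lower at 4.5 µg/mL, and 2 were higher and 1 lower at 9.0 µg/mL. CNAG_05847, thioredoxin reductase, stood at 232, 700 and 694 TPM. CNAG_05256, a catalase, stood at 10.6, 21.3 and 32.6 TPM, and CNAG_06917, a thiol peroxidase, at 28.6, 44.5 and 67.1 TPM. CNAG_04981, another catalase, was lower, with 76.0, 40.1 and 50.6 TPM. The relative list median was 0.10 and -0.15, at percentiles 93.6 and 61.9. The relative mean was 0.096 and 0.10, so median and mean differed in sign at 9.0 µg/mL. Without subtracting the median of all genes, the list median at 9.0 µg/mL was 0.31, against 0.25 in the matched random lists.

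Cell wall genes stayed close to the median gene. Of 15 listed cell wall genes above the filter, none was 2-fold apart at 4.5 µg/mL and 3 were 2-fold higher at 9.0 µg/mL, of which 1 remained so relative to the median gene. The list medians of -0.037 and 0.15 lay at percentiles 21.8 and 70.3 of the matched lists. The exception was CNAG_06291, a chitin deacetylase family gene, with 9.38 TPM in the control, 14.1 TPM at 4.5 µg/mL and 31.5 TPM at 9.0 µg/mL. Of the chitin synthases, CNAG_05818 had 3.77, 5.60 and 9.38 TPM and CNAG_03326 had 7.12, 10.7 and 15.3 TPM. The others had relative log2 changes of 0.090 and 0.19 (CNAG_03099), -0.12 and -0.30 (CNAG_05581), -0.20 and 0.15 (CNAG_00546), 0.30 and 0.23 (CNAG_06487) and -0.089 and -0.16 (CNAG_07499). CNAG_02217 was under the filter, with 1.32, 2.02 and 1.97 TPM. The glucan synthases CNAG_06508 and CNAG_03120 were at 0.17 and 0.24 and at -0.039 and 0.040. The glucan assembly genes CNAG_00914 and CNAG_00897 were at -0.037 and -0.50 and at -0.39 and -0.53. The chitin deacetylases CNAG_05799, CNAG_01230 and CNAG_01239 were at -0.020 and 0.15, -0.27 and -0.20, and -0.35 and -0.20.

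None of the 6 listed capsule genes was 2-fold apart at either dose. Their list medians were -0.053 and -0.11, at percentiles 54.1 and 67.1. CNAG_03322, which makes the UDP-xylose precursor, had the value furthest from the median gene, with 305, 271 and 271 TPM.

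**Figure D3:**
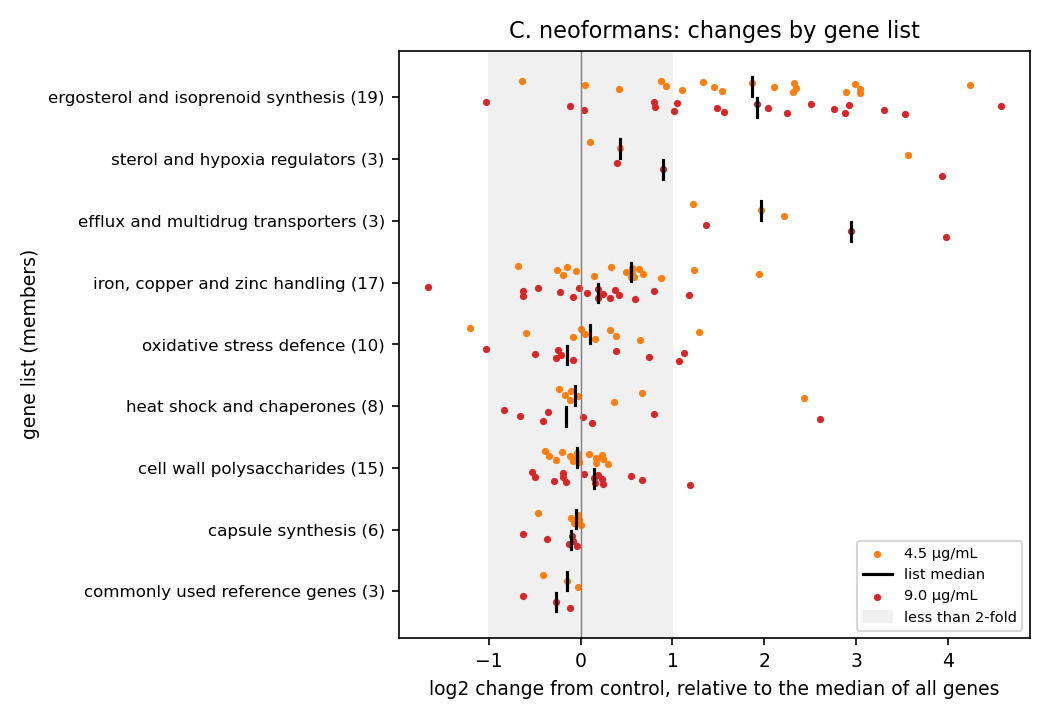
Log2 change from control relative to the median of all genes (x axis) for the members of 9 C. neoformans gene lists at 4.5 µg/mL and 9.0 µg/mL, 1 point per gene, with black bars at list medians and vertical offsets only to separate points. The ergosterol medians of 1.87 and 1.92 lie outside the shaded 2-fold band, and those of cell wall, capsule, chaperone and oxidative stress genes lie inside it.

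The second question was how the doses differed. Between 4.5 and 9.0 µg/mL, 112 genes were at least 2-fold higher and 24 at least 2-fold lower at the higher dose. Centred on a median gene 0.18 higher, these counts were 71 and 47, or 60.2% higher against 82.4% without centring. CNAG_06672 had the largest difference, with 9.56 TPM in the control, 49.96 TPM at 4.5 µg/mL and 675 TPM at 9.0 µg/mL. CNAG_04523 stood at 4.23, 4.09 and 37.8 TPM. CNAG_00735 was lower at the higher dose, with 21.4, 32.5 and 7.10 TPM, as was CNAG_00597. Of the 358 genes higher at both doses, 315 were higher at 9.0 than at 4.5 µg/mL, as were 76.7% of all genes. In the ergosterol list 11 of 19 genes were higher at 9.0 µg/mL, and the median step was 0.18 on the log2 scale, or -0.0016 relative to the median gene, with 9 of 19 above it. Against random lists matched on expression, whose median was 0.036, the list lay at percentile 97.1. The matching included the treated libraries, so raised genes were set against more abundant ones. The median step was 0.028 in expression decile 9 and -0.034 in decile 10, against 0.18 over all genes. The percentile therefore says little about the step of this list. The median step of the metal list was -0.22, below all 10000 matched random lists. Of its 17 members above the filter, 5 had a positive step. The largest was that of CNAG_05449, with 243 TPM in the control, 262 TPM at 4.5 µg/mL and 418 TPM at 9.0 µg/mL.

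Changes at the 2 doses were correlated across genes (Pearson's r = 0.87, Spearman's rho = 0.83, 6197 genes, which are not independent replicates). The value depends on the common reference, with r = -0.18 when the 4.5 µg/mL library takes the place of the control and r = 0.64 when the 9.0 µg/mL library does. Both comparisons use the same control library. In simulations of unchanged libraries this alone gave r = 0.50, a value fixed in advance because every library was given the same spread. The covariance was 0.31 against 0.053 in the simulations, a difference of 0.26. For genes at least 2-fold higher, independent lists would share 58.1 genes, against 358 observed. The simulations shared 0.70, but their spread lets few genes reach 2-fold, so that count says little about the shared control. The simulated control had the spread seen between the doses, so an odd control library was not simulated. An odd control library alone, with only independent noise between the doses, would give a positive r with the 4.5 µg/mL library as reference. The value of -0.18 argues against that as the whole cause across these 6197 genes. With 1 control library, part of the excess can still come from that library.

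The third question was how M. restricta transcript levels differed after 12 hours at 3.0 mg/mL. Differences were small. Of 4383 genes, 2 were at least 2-fold higher and 62 at least 2-fold lower, and 92.4% lay within 1.5-fold of the control. Centred on the median gene, 5 were higher and 43 lower. The highest were MRET_4390, with 192 TPM in the control and 420 TPM after treatment, and MRET_1111, with 135 and 281 TPM. The lowest were MRET_2222, with 336 and 73.1 TPM, and MRET_3990, with 365 and 88.5 TPM. The median gene had a log2 change of -0.075 (95% bootstrap interval over genes -0.084 to -0.066). None of the 438 genes in the highest expression decile was 2-fold apart, and their median log2 change was 0.085. That decile held 51.3% of all TPM in the control and 55.0% after treatment. Gene functions were not assigned in this species.

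The series title names a comparison between the species. The standard deviation of log2 changes across genes was 0.53 and 0.68 at the 2 C. neoformans doses and 0.32 in M. restricta. Genes at least 2-fold apart made up 6.57%, 15.2% and 1.46% of those measured. The median of all genes lay above 0 in C. neoformans and below 0 in M. restricta. The 50 most abundant genes had a median log2 change of -0.32 and -0.56 in C. neoformans and 0.13 in M. restricta. Dose, medium, temperature and duration all differed between the species, so these values stand side by side and were not tested against each other.

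**Figure D4:**
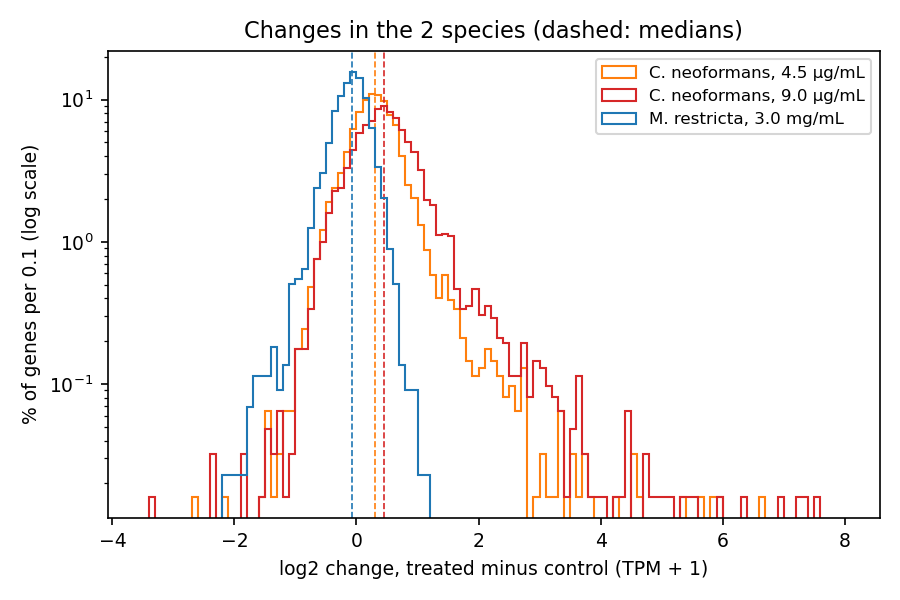
Percentage of genes (log axis) per 0.1 of log2 change from control for C. neoformans at 4.5 and 9.0 µg/mL and for M. restricta at 3.0 mg/mL, with dashed lines at the medians of 0.30, 0.46 and -0.075. The C. neoformans distributions have a long upper tail reaching 6.63 and 7.60, and that of M. restricta ends at 1.12.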

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

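The tests of explanations in this part were chosen only after the results were seen. The median gene lay on opposite sides of 0 in the 2 species under lauryl betaine. The median log2 change of all genes was 0.30 at 4.5 µg/mL and 0.46 at 9.0 µg/mL in C. neoformans and -0.075 in M. restricta. Rescaling without the 50 most abundant genes gave medians of 0.17 at 4.5 µg/mL and 0.26 at 9.0 µg/mL, and -0.044 in M. restricta. With 1 library per condition, this difference was not tested.

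In C. neoformans the shift may be partly arithmetic, because TPM has a fixed sum and the abundant genes were lower. A single scale factor from lower abundant genes would move all other genes alike, but at 9.0 µg/mL the median change was 0.70 in the lowest expression decile and 0.30 in decile 8, a difference of 0.40 (95% bootstrap interval 0.34 to 0.46), which argues against one factor as the whole cause. A uniform background such as genomic DNA would add equal TPM to every gene. The 265 genes with a control TPM under 1, however, gained a median of 0.35 TPM against 3.78 TPM in the lowest expression decile. That decile holds only genes with a mean TPM of at least 5, treated libraries included. Some of them can have passed this filter through their gain, so part of the contrast can come from selection. Changes were larger in longer genes, with Spearman's rho of 0.16 between length and change across genes. The 1240 shortest genes had a median of 0.34 (0.31 to 0.38), against 0.53 in the 1239 longest. Because the TPM sum is fixed, a positive median in the shortest genes does not bound a length effect, so this value cannot decide. Between the treated libraries, without the control, the median gene was also 0.18 higher at 9.0 than at 4.5 µg/mL and 47 of the 50 most abundant genes were lower, but with 1 library per dose a response of C. neoformans to the compound and differences peculiar to single libraries both stay open.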

How the results depend on the processing

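Centred on the median gene, the 2-fold counts were 217 higher and 73 lower at 4.5 µg/mL, 376 higher and 148 lower (524 in all) at 9.0 µg/mL, 71 higher and 47 lower between the doses, 196 higher and 36 lower (232 in all) at both doses, and 5 higher in M. restricta. Rescaling without the 50 most abundant genes gave 32 lower at 4.5 µg/mL, 40 lower at 9.0 µg/mL and 4 higher in M. restricta. At 9.0 µg/mL a pseudocount of 5 TPM gave 611 genes, 595 of them higher, and a mean TPM of at least 20 gave 575, 559 of them higher. The former compresses and the latter removes low genes. Every other total stayed within 1.5 times the reported count. The number of ergosterol genes at least 2-fold higher did too under every alternative. Counts within other gene lists, and in the ergosterol list between the doses, were compared in the same way. Of these alternative values, 103 stayed within 1.5 times and 9 did not. The 103 include counts of 0 that stayed at 0, so they overstate how stable the other list counts are. Among the 9 were the cell wall genes 2-fold higher at 9.0 µg/mL, 3 as reported and 1 after centring. The correlation between doses depends on the common reference library. It was -0.18 with the 4.5 µg/mL library and 0.64 with the 9.0 µg/mL library as reference. Of list medians, 123 of 126 alternative values kept their side of the percentile limits, and the other 3 crossed to above the upper one. Centring shifts a list and its random lists alike, so it cannot change a percentile, and rescaling hardly can. The 123 therefore overstate how stable the list medians are. For all listed genes and the genes named by size there were 1204 alternative values. Of these, 1169 kept their side of the 2-fold limit, 26 crossed to below it, 9 crossed to above it and none of those beyond it changed sign. The listed genes include some under the filter and some not named above, so the 1169 are no measure for the named genes alone. No paired analysis was possible because each group has 1 library. Unknown depth limits the reading of genes near the filter most.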

Other observations

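Further C. neoformans genes listed in advance fell outside the groups above. CNAG_01539, inositol phosphate synthase, which supplies phospholipid synthesis, stood at 236 TPM in the control, 662 TPM at 4.5 µg/mL and 926 TPM at 9.0 µg/mL. CNAG_06085, the secreted phospholipase, stood at 24.9, 65.9 and 125 TPM. CNAG_05540, urease, stood at 75.2, 84.7 and 86.9 TPM. The laccases CNAG_03465 and CNAG_03464 were under the filter, with 3.40, 4.71 and 3.88 TPM and with 2.10, 3.29 and 4.34 TPM. Among genes often used as references, CNAG_00483, actin, stood at 918, 1021 and 1049 TPM and CNAG_06125, an elongation factor, at 11579, 10741 and 10271 TPM. CNAG_06699, a glycolytic dehydrogenase, stood at 3709, 4488 and 4708 TPM. Relative to the median gene all 3 were lower at both doses, although actin and the dehydrogenase had more TPM than in the control.

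The 13 protein-coding genes of the C. neoformans mitochondrial genome summed to 2.32 TPM in the control, 3.34 TPM at 4.5 µg/mL and 4.57 TPM at 9.0 µg/mL, and none exceeded 2.33 TPM. Of these genes 3, 2 and 1 were listed at 0. Whether mitochondrial reads were removed or depleted before counting is not given in the sources used here, so these values do not give mitochondrial transcript levels. The median change of single nuclear chromosomes ran from 0.27 to 0.35 at 4.5 µg/mL and from 0.41 to 0.50 at 9.0 µg/mL over 14 chromosomes, so no chromosome stood apart.

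The tests on the ergosterol list were chosen after its values were seen. Its position is not explained by one scale factor from the fixed TPM sum, since its median at 9.0 µg/mL was still 1.92 after centring (95% bootstrap interval over its genes 1.02 to 2.76). An odd control library would give the same picture without any effect of dose. The step from 4.5 to 9.0 µg/mL does not use the control. It put the list at percentile 97.1 of matched random lists, within their middle 95%, and a pseudocount of 5 TPM put it just outside. The matching used treated values, so this percentile cannot decide. Relative to the median gene the median step of the list was -0.0016. With 1 control library, an odd control and a response to lauryl betaine cannot be told apart for this list. A hypothesis that further control and treated libraries would test is that the sterol-responsive regulator and its pathway respond to the compound.

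For the pattern of M. restricta neighbours, found in these data, the tests of its origin were written down before their results were seen. In M. restricta, genes with consecutive identifiers had similar changes. Spearman's rho between a gene and the next identifier was 0.29 over 4375 pairs, computed across genes, which are not independent replicates, and lay above the highest of 1000 permutations of the order (0.049, permutation p = 0.001, the smallest they can give). Of the 62 genes at least 2-fold lower, 16 had another such gene as a direct neighbour by number, against a mean of 1.71 and a highest count of 14 in 10000 random draws. Reads shared between overlapping neighbours would end at adjacent genes, but rho was still 0.23 at a distance of 2 and 0.11 at a distance of 10. Similar abundance of neighbours does not account for it, since rho was 0.29 after abundance was removed, and abundance itself gave 0.077. If the identifiers follow the chromosomes, which was not checked here, a regional effect may be present, from the cells or from base composition, which was not tested. In C. neoformans, neighbours in the reference order gave rho of 0.097 and 0.088 across 6183 pairs of genes.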
